A study of Mus musculus with 4 samples.

How the data were processed

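RNA was extracted from somitic gastruloids with a column kit and DNase treatment, and libraries were made from 250 to 500 ng of RNA with the KAPA RNA HyperPrep kit after ribosomal RNA depletion (RiboErase), with fragmentation at 94 °C for 6 min and 6 to 10 cycles of PCR, per the labels' protocols. Fastp 0.20.1, STAR 2.7.6a, HTSeq 0.12.4 and DESeq2 1.34.0 and the builds GRCm38.p6 and mm10 are named in the submitters' processing notes, without their roles. The annotation used for counting, the strand setting and the read length are not given in the sources used here. The deposited values are raw whole-number counts of reads per gene symbol, in 1 table per library with no normalization, and HTSeq summary lines stand at the end of each table as its values show. Reads of near-identical gene copies and of genes that overlap on opposite strands are uncertain in such counts. The mitochondrial genes COX2, COX3 and ATP6 and the nuclear gene Jund had 0 or 1 counts in every library, where COX1 had 78133 to 101453, so their values were not read as expression.

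Samples were grouped by their titles into untreated and dTAG-13, with 2 libraries each. The tables list 24831 genes, and the summary lines were left out of library sizes and tests. Shares were taken of the reads counted in genes, outside genes or as ambiguous. The share of reads counted outside genes was 35.65% in untreated replicate 1 (95% exact binomial interval 35.63% to 35.67%), 24.12% in untreated replicate 2, 25.3% in dTAG-13 replicate 1 and 29.23% in dTAG-13 replicate 2, and ambiguous reads were 0.209% to 0.240%. Such intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Counts of the replicates of a group were compared to see whether 1 library had been deposited under both names. The values exclude this (chi-square per degree of freedom of 36.3 for the untreated pair and 30.9 for the dTAG-13 pair). They do not show what caused the spread, and they are set beside those of same-numbered libraries further below.

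The main test was edgeR 4.0.16 in R 4.3.3 on the counts as deposited: filterByExpr with the group (minimum count 10, minimum total 15), TMM factors, estimateDisp, glmQLFit with robust estimation and a two-sided glmQLFTest, with Benjamini-Hochberg adjustment over the 13602 genes kept and a threshold of 0.05. All 4 libraries entered the fit, with the group as the only term. The square root of the common dispersion was 21.7%, with 2 residual degrees of freedom and a median of 4.47 prior ones. Standard errors are the absolute log2 fold change divided by the square root of the test's F. CPM values use the TMM library sizes, and log2 CPM values for list tests and for differences within a replicate number add a prior count of 2. A difference within a number is dTAG-13 minus untreated between the libraries that carry that number.

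The groups, the test, 34 gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, apart from the alternative without members shared between lists and the surface ectoderm list, which came later. Lists with at least 5 genes kept (32 of them) were tested with camera of limma 3.58.1 on log2 CPM, two-sided, at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over those lists; list p-values in the text are adjusted in this way. Camera compares a list with all other genes. Counts of members past 0.05 were also taken with the adjustment over the list alone, and these are the calls meant where a member of a list is said to rise or fall. Where no other tool is named, counts over a list or over all genes are edgeR's with the group as the only term. Older gene symbols were matched through the RefSeq gene table of GRCm38.p6, from which the coordinates also come.

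Genes were named by rule: Zeb2 and Zeb1, and the 10 genes of largest change in each direction among those past the threshold with an average log2 CPM of at least 1 and the same direction in both numbers. Since none passed, the 5 with the smallest p in each direction were given as values. In each list the examples were the members with the smallest p and an average log2 CPM of at least 0, 4 where a member passed over the list alone and 2 where none did. That reading of the threshold was adopted because no gene passed over all genes. Some lists give fewer examples, and genes outside the rule are named as such.

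The test was tried on simulated data before use, with counts drawn for the real genes from the real means and library sizes and 100 genes changed by 2-fold and 100 by 4-fold among 13471 genes. With the observed difference between replicate numbers in the counts and no term for it, 5% and 74% were recovered with 0 false calls; a simulation of 13415 genes without that difference gave 46% and 91% with 6 false calls. With no gene changed, 0 genes were called. List tests were tried on lists of 18 genes, 20 of them shifted by 0.6 on the log2 scale.

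Alternatives were RLE or upper quartile factors, no filter or at least 50 counts in 2 libraries, the legacy quasi-likelihood fit, DESeq2 1.42.0 with its own filtering, thresholds of 0.01 or with an absolute log2 fold change of 1, leaving out mitochondrial genes and the 50 genes with most counts, thinning to the smallest library, the replicate number as a block in edgeR, DESeq2 and fry, an estimated correlation in camera, fry, and leaving out each library. A lone library left in a group was assumed to vary like the other group. Such a fit leaves the replicate numbers unequal between the groups, so a difference between numbers enters its values. GC content and length were taken from GENCODE M21 transcripts with Biostrings 2.70.1, and matched 97.5% of the genes kept. Intervals of medians are from 10000 bootstrap draws over genes, which are not independent replicates.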

Results

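The series measured gene expression by RNA sequencing in mouse somitic gastruloids, aggregates of embryonic stem cells that form an elongating structure with presomitic tissue and somites in culture. The cells were E14 embryonic stem cells carrying a triple reporter, with both an HA epitope and the FKBP12 F36V degron fused to the endogenous Zeb2 gene. Zeb2 encodes a zinc finger transcription factor known as a repressor of epithelial genes and a partner of SMAD proteins. dTAG-13 is a small molecule that binds the degron and recruits a ubiquitin ligase, so that the tagged protein is degraded. Gastruloids were started from 300 cells per well, exposed to 3 μM CHIR99021, an activator of WNT signalling, from 48 h, and embedded in 10% Matrigel at 96 h. One group received 100 nM dTAG-13 at 72 h and 96 h. The other is labelled untreated, and the growth protocol names DMSO as the control. Each group held 2 libraries, numbered 1 and 2 in both. Reads counted in genes came to 12716172 and 11566746 in untreated replicates 1 and 2, and to 12230908 and 11491330 in dTAG-13 replicates 1 and 2. A total of 13602 genes had enough counts to be tested. No label says whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

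The comparison asked which transcripts differ once the ZEB2 protein is removed, and the tagged gene was examined first. Zeb2 mRNA (chromosome 2, 44983512 to 45117442 in GRCm38.p6) was at 98.3 and 164 CPM, the depth-normalised read count, in the untreated libraries and at 103 and 108 CPM in the dTAG-13 libraries. Its group means were 131.1 ± 46.4 CPM and 105.3 ± 3.93 CPM (SD, n = 2 each), a log2 fold change of -0.31 ± 0.25 (SE) with an adjusted p of 1.00 by edgeR. The sign of this value rested on single libraries, since it was 0.10 without untreated replicate 2. dTAG-13 acts on the protein, which these data do not measure, so the level of Zeb2 mRNA does not check the labels. The antisense gene Zeb2os overlaps Zeb2 in the annotation and was not analysed here, and the strand setting of the counting is not given in the sources used here. Zeb1, its paralog and also a repressor of epithelial genes (chromosome 18, 5591327 to 5775468), was at 84.6 and 56.0 CPM in the untreated libraries and at 59.9 and 26.1 CPM with dTAG-13, a log2 fold change of -0.71 ± 0.46 (adjusted p = 1.00) that ranged from -0.25 without dTAG-13 replicate 2 to -1.43 without dTAG-13 replicate 1.

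Genes of epithelial cells were higher with dTAG-13 and genes of neural tube progenitors, somites and the anterior Hox groups were lower. The list of epithelial genes known as targets of ZEB repression had a median 2.23-fold above untreated, with 32 of its 33 measured members higher and 31 higher in both replicate numbers. Neural tube progenitor genes had a median 2.02-fold below untreated, with all 20 measured members lower and 19 lower in both numbers. Somite genes were a median of 1.50-fold lower, with 16 of 16 measured members below untreated and 14 below it in both numbers. Hox genes of groups 1 to 4, which are expressed from the hindbrain to the anterior trunk, were a median of 1.48-fold lower, with 11 of 12 members below untreated in both numbers. No single gene passed an adjusted p of 0.05 over all 13602 genes in edgeR's quasi-likelihood test with the group as its only term. The smallest adjusted p was 0.756, and 473 genes had an unadjusted p under 0.05, 305 higher and 168 lower, against 680 that chance alone gives. DESeq2 on the same counts called 41 genes, 27 higher and 14 lower. With the replicate number as a block edgeR called genes in both directions, as given further below, so the count of 0 depends on leaving the number out. Among 32 lists tested against all other genes with camera at a preset correlation, 19 passed an adjusted p of 0.05, 9 higher and 10 lower. With a correlation estimated from these libraries 0 of the 32 passed, and the smallest adjusted p was 0.416, and fry, which asks whether a list moves one way, passed 0 with a smallest adjusted p of 0.323.

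In the epithelial list, 22 of 33 members rose in edgeR when adjusted over the list alone and 0 passed over all genes tested. The other 11 passed neither. Over all genes, DESeq2 called Krt8, Krt18, Cldn7, Cldn6, Rab25 and Ap1m2. The list test gave an adjusted p of 5.34e-25, and adjusted p = 0.416 with an estimated correlation. The keratins Krt8 and Krt18, which pair in the intermediate filaments of simple epithelia and lie side by side on chromosome 15 (101996711 to 102004342 and 102028216 to 102032026), rose by log2 values of 1.40 ± 0.27 and 1.08 ± 0.22 (both adjusted p = 0.0246 over the list alone). Krt8 was at 71.7 and 63.8 CPM in the untreated libraries and at 133 and 226 CPM with dTAG-13. Cldn7, a tight junction protein, rose 3.05-fold from 14.3 ± 0.473 to 43.8 ± 18.9 CPM (SD, n = 2 each), and Patj, a scaffold of the apical polarity complex, rose 1.63-fold from 57.5 ± 4.61 to 94.0 ± 5.17 CPM. The log2 fold change of Cldn7, 1.61 with all libraries, was 1.07 without dTAG-13 replicate 2. Epcam and Cdh1 were singled out after their values were seen. Epcam, an adhesion molecule of epithelia, went from 112 ± 25.04 to 214.7 ± 75.6 CPM and rose over the list alone (adjusted p = 0.0419), while Cdh1, which encodes E-cadherin, had 174 and 310.3 CPM untreated and 302 and 620 CPM with dTAG-13 and did not pass. The median log2 fold change of the list was 0.89 in replicate number 1 and 1.39 in number 2. The members called over the list alone fell from 22 to 0 without untreated replicate 1, without untreated replicate 2 or without dTAG-13 replicate 2, while the median stayed between 0.66, without dTAG-13 replicate 2, and 1.48. The list test held without any one library.

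**Figure D1:**
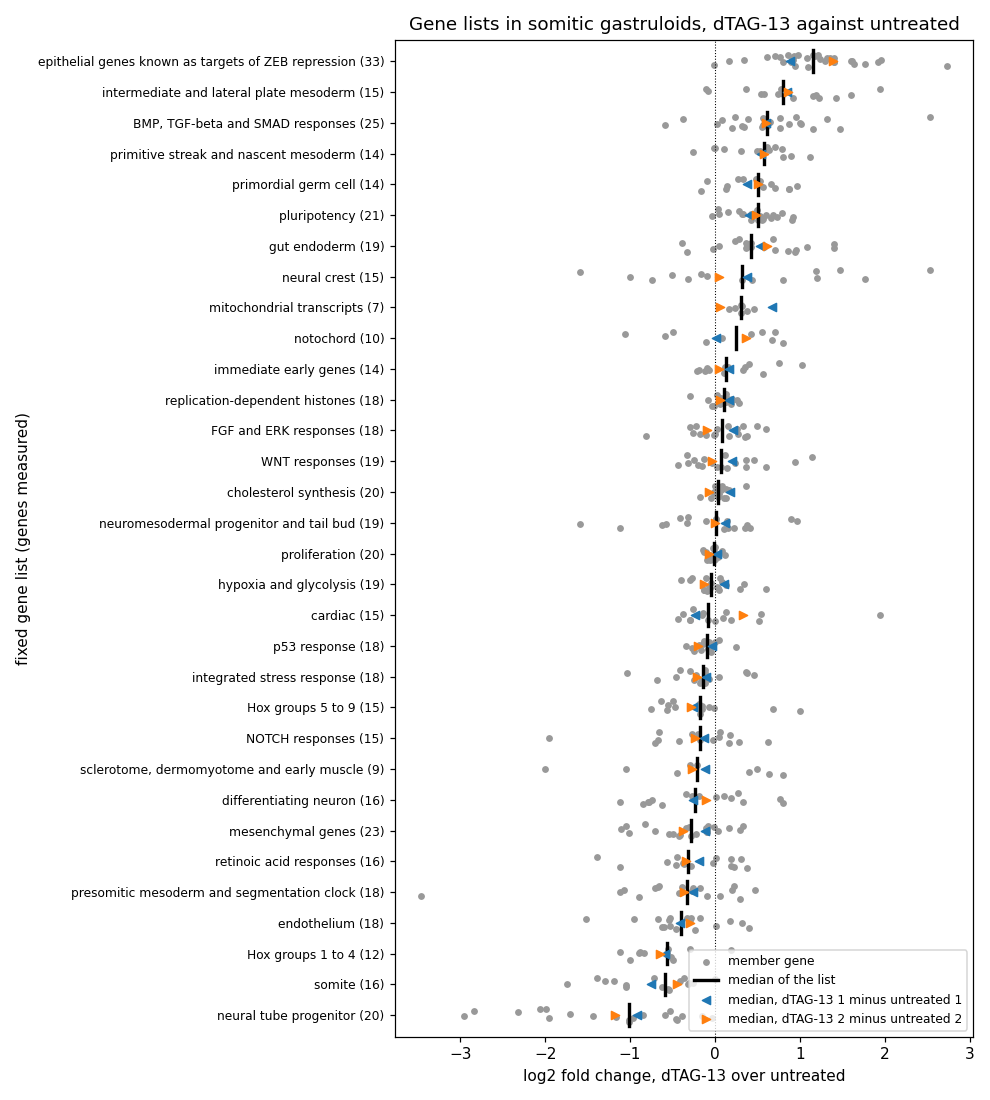
Log2 fold change of dTAG-13 over untreated for the measured members of each of 32 gene lists (grey points), with the median of each list (black bar) and its median in replicate number 1 (blue triangle) and number 2 (orange triangle). Epithelial genes have the highest median, 1.16, and neural tube progenitor genes the lowest, -1.01.

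Among neural tube progenitor genes, 10 of 20 fell in edgeR when adjusted over the list alone and 0 over all genes tested. DESeq2 called members of the list over all genes, Irx3 and Ptn among them. Camera gave an adjusted p of 8.13e-19, and adjusted p = 0.416 with an estimated correlation. Pou3f2, a neural POU factor, fell from 4.95 ± 0.177 to 1.23 ± 0.0642 CPM, and Irx3, a homeobox gene of the neural tube, fell from 57.6 ± 14.8 to 28.4 ± 2.14 CPM (SD, n = 2 each). Ptn, a secreted growth factor, fell by 0.85 on the log2 scale and Nkx6-1, a ventral neural tube homeobox gene, by 2.06 (all 4 at an adjusted p of 0.0145 over the list alone). Sox2, which is shared with other progenitors and was picked after its values were seen, had 104 and 204 CPM untreated and 95.6 and 139 CPM with dTAG-13 and did not pass. The number that fell was 6 with the filter of at least 50 counts, 0 without untreated replicate 2 or without dTAG-13 replicate 2 and 2 without dTAG-13 replicate 1, and the median log2 fold change, -1.01 with all libraries, was -0.63 without untreated replicate 2 and -1.54 without dTAG-13 replicate 2. Genes of differentiating neurons had a median of -0.23 and 0 of 16 members passed. The Onecut2 transcription factor gene had a log2 fold change of -0.79 ± 0.27 and Elavl4, a neuronal RNA-binding protein, of -0.74 ± 0.32. Their list test had an adjusted p of 0.0477, with adjusted p = 0.416 with an estimated correlation, and missed 0.05 without untreated replicate 1, untreated replicate 2 or dTAG-13 replicate 1 (highest 0.206). It also missed 0.05 with RLE (0.0579) or upper quartile factors (0.0832), at least 50 counts (0.1865), thinned counts (0.0959), or without mitochondrial and the 50 highest genes (0.0746). The median of that list was -0.455 without dTAG-13 replicate 1.

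Of the 16 somite genes measured, 2 fell when adjusted over the list alone and 0 over all genes (list test adjusted p = 9.73e-08; adjusted p = 0.416 with an estimated correlation). Tcf15, a transcription factor needed for somites to become epithelial, fell from 9.80 ± 0.228 to 4.0 ± 0.228 CPM, and Fst, which encodes follistatin, fell from 60.4 ± 5.83 to 39.2 ± 0.716 CPM (SD, n = 2 each). Foxc2 and Pax3 had log2 fold changes of -1.04 ± 0.32 and -0.72 ± 0.24 and did not pass. Leaving out any one library took the count of 2 to 0, and the median, -0.59 with all libraries, was -0.94 without untreated replicate 2 and -1.10 without dTAG-13 replicate 1. Genes of the presomitic mesoderm and segmentation clock had a median of -0.32, and 1 of 18 fell over the list alone and 0 over all genes. It was Ripply2, a repressor that acts at segment borders, at 1.66 and 1.33 CPM untreated and 0.0853 and 0.170 CPM with dTAG-13; it lies below the expression level set for examples and was chosen after its values were seen. Hes7, the oscillating repressor of the clock, had 23.1 ± 1.38 and 14.2 ± 0.648 CPM, and Dll1, Pcdh8 and Tbx6 had log2 fold changes of -0.66, -1.07 and -0.90; none of these passed over the list alone. The list test had an adjusted p of 3.60e-05, or adjusted p = 0.425 with an estimated correlation, and it missed 0.05 without dTAG-13 replicate 2 (0.0649). The median was -0.14 without untreated replicate 1, -0.09 without dTAG-13 replicate 2 and -0.61 without dTAG-13 replicate 1. Leaving out any one library or asking for at least 50 counts took the single call to 0, and 3 members fell with upper quartile factors, with no filter or without mitochondrial and the 50 highest genes, and 4 with DESeq2.

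Among derivatives of somites, 9 members were measured and the list test did not pass (adjusted p = 0.472). Over the list alone 1 member fell and 1 rose, and 0 passed over all genes in edgeR. Over all genes, DESeq2 called the member that fell (adjusted p = 0.00446). Dmrt2, a transcription factor of the dermomyotome, fell 3.99-fold from 10.7 ± 0.818 to 2.68 ± 0.0515 CPM (adjusted p = 0.00444 over the list alone), and Sox9, known in cartilage precursors, notochord and neural crest, rose 1.74-fold (0.0495). The rise of Sox9 was lost without untreated replicate 1, untreated replicate 2 or dTAG-13 replicate 1, and also with no filter, with thinned counts and without mitochondrial and the 50 highest genes.

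Hoxc4 and Hoxb3 were the 2 of 12 members of Hox groups 1 to 4 that fell in edgeR when adjusted over the list alone, with 0 over all genes. DESeq2 called both over all genes (adjusted p = 0.00255 and 0.0499). Hoxc4 (chromosome 15, 103018097 to 103036856) fell from 61.5 ± 0.964 to 30.7 ± 2.93 CPM and Hoxb3 from 117 ± 25.6 to 63.3 ± 10.4 CPM (SD, n = 2 each). DESeq2 called 4 over the list alone. Hoxa3 and Hoxb2 had log2 fold changes of -0.57 ± 0.18 and -0.50 ± 0.17 and did not pass. The list test gave an adjusted p of 3.38e-07, and adjusted p = 0.416 with an estimated correlation. Hox groups 5 to 9, expressed further back in the trunk, had a median of -0.17 with 0 of 15 members passing. Hoxc8 and Hoxa9 had log2 fold changes of -0.55 and -0.47, and the list had an adjusted p of 0.0205, with adjusted p = 0.416 with an estimated correlation, and it missed 0.05 without untreated replicate 2 (0.152) or dTAG-13 replicate 2 (0.186). The median of groups 5 to 9 was -0.27 without untreated replicate 1, -0.11 without untreated replicate 2 and -0.40 without dTAG-13 replicate 1. Of groups 10 to 13 only 3 members were measured, too few for a test; Hoxa10 was at 5.57 and 1.51 CPM untreated and 8.79 and 3.74 CPM with dTAG-13. Retinoic acid responses had a median of -0.31 and 0 of 16 members passed (adjusted p = 0.0203, or adjusted p = 0.416 with an estimated correlation), and their test missed 0.05 without untreated replicate 2 (0.352) or dTAG-13 replicate 1 (0.142). Their median was -0.03 without untreated replicate 2 and -0.21 without dTAG-13 replicate 1. The test also missed 0.05 without members shared with other lists (0.0522), and DESeq2 called 2 members over the list alone and Crabp2 over all genes. Crabp2, a retinoic acid binding protein, was at 101 and 180.2 CPM untreated and 46.1 and 61.6 CPM with dTAG-13, and Hoxb1 had a log2 fold change of -1.12 ± 0.37. NOTCH responses had a median of -0.17 and 0 of 15 passed (adjusted p = 0.0108, or adjusted p = 0.599 with an estimated correlation), and their test missed 0.05 without untreated replicate 1 (0.220) or dTAG-13 replicate 2 (0.664), where the median turned to 0.01 and 0.07. It was -0.39 without untreated replicate 2 and -0.55 without dTAG-13 replicate 1. Without its 8 members shared with other lists, the NOTCH test turned direction and missed 0.05 (0.438), and DESeq2 called 2 members over the list alone. Hes5, a NOTCH target of neural progenitors that also stands in the neural list, had a log2 fold change of -1.96 ± 0.44.

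Gut endoderm genes had a median log2 fold change of 0.42, and 5 of 19 measured members rose in edgeR when adjusted over the list alone, with 0 over all genes (list test adjusted p = 2.37e-06, or adjusted p = 0.416 with an estimated correlation). Of these 5, Krt8, Krt18 and Cldn6 also belong to the epithelial list, and DESeq2 called these over all genes. Foxa2, a transcription factor of endoderm and notochord, rose 1.63-fold from 15.9 ± 1.13 to 26.0 ± 3.65 CPM, and Apela, a peptide hormone, rose 1.60-fold from 14.3 ± 0.643 to 22.9 ± 0.255 CPM (SD, n = 2 each, adjusted p = 0.0481 over the list alone for both). The count was 2 with RLE or upper quartile factors, no filter, at least 50 counts, the legacy fit, thinned counts, or without mitochondrial and the 50 highest genes. It was 7 with DESeq2, 4 without either dTAG-13 library and 0 without untreated replicate 1 or without untreated replicate 2. The median was 0.76 without untreated replicate 1, 0.67 without dTAG-13 replicate 2 and 0.24 without dTAG-13 replicate 1. The primitive streak and nascent mesoderm list had a median of 0.57 with 0 of 14 members past the threshold (adjusted p = 4.20e-05; adjusted p = 0.416 with an estimated correlation), and Evx1 was at 10.5 ± 1.29 and 19.4 ± 2.65 CPM. That median was 0.34 without untreated replicate 2 and 0.32 without dTAG-13 replicate 1, and without the 9 members shared with other lists the test missed 0.05 (0.0564). Pluripotency genes had a median of 0.50 with 20 of 21 members higher and 0 past the threshold (adjusted p = 2.99e-07; adjusted p = 0.437 with an estimated correlation). L1td1 and Tbx3 had log2 fold changes of 0.61 ± 0.17 and 0.91 ± 0.20, and the median was 0.08 without dTAG-13 replicate 2, 0.26 without untreated replicate 1 and 0.79 without dTAG-13 replicate 1. Over the pluripotency list alone DESeq2 called 3 members, and edgeR 1 with no filter and 2 without dTAG-13 replicate 1. Primordial germ cell genes had a median of 0.51 with 0 of 14 past the threshold. Their adjusted p was 4.72e-04, or adjusted p = 0.437 with an estimated correlation, and it missed 0.05 without untreated replicate 1 (0.0736) or dTAG-13 replicate 2 (0.161), where the median was 0.30 and 0.11. Dnd1 and Ifitm3 had log2 fold changes of 0.71 ± 0.35 and 0.49 ± 0.24.

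BMP, TGF-beta and SMAD responses had a median log2 fold change of 0.62, with 23 of 25 members higher, 1 that rose in edgeR over the list alone and 0 over all genes (list test adjusted p = 1.50e-07, or adjusted p = 0.416 with an estimated correlation). That member was Msx2, a homeobox target of BMP signalling, at 1.71 ± 0.780 CPM untreated and 10.2 ± 1.59 CPM with dTAG-13 (SD, n = 2 each, adjusted p = 0.0139 over the list alone); it did not pass without untreated replicate 1 or without untreated replicate 2. DESeq2 called Msx2 over all genes (adjusted p = 0.00255). Bmp2, Smad6 and Bambi had log2 fold changes of 1.00 ± 0.32, 1.01 ± 0.34 and 0.77 ± 0.21. The median was 1.05 without untreated replicate 1, 0.35 without untreated replicate 2 and 0.33 without dTAG-13 replicate 1. Intermediate and lateral plate mesoderm genes had a median of 0.80, and 1 of 15, Tbx3, rose over the list alone (1.88-fold, adjusted p = 0.0455) and 0 over all genes. Their list test had an adjusted p of 0.00160, or adjusted p = 0.649 with an estimated correlation. It was lost without untreated replicate 2 (0.785) and without dTAG-13 replicate 1 (0.663), where the median was 0.32 and -0.54. It was 2.07 without untreated replicate 1 and 1.43 without dTAG-13 replicate 2. The test also missed 0.05 without members shared with other lists (0.0522). The call of Tbx3 was lost without any one library, with upper quartile factors, with thinned counts and without mitochondrial and the 50 highest genes. Hand1, Emx2 and Bmp4 had log2 fold changes of 1.94 ± 1.28, 1.22 ± 0.90 and 1.16 ± 0.55. Without dTAG-13 replicate 1 these were 0.14, -0.34 and 0.48, and without untreated replicate 1 they were 8.11, 2.11 and 1.90. Hand1 was at 0 CPM in untreated replicate 2, the only untreated library then left, so its 8.11 does not measure a fold. The neural crest list did not pass (adjusted p = 0.0815), with 4 of 15 members higher and 2 lower in edgeR over the list alone and 0 over all genes. Of this list, DESeq2 called Msx2 and Erbb3 over all genes. Erbb3, a neuregulin receptor, rose from 31.7 ± 4.93 to 72.7 ± 19.3 CPM and Tfap2a, a transcription factor of neural crest and surface ectoderm, from 3.35 ± 1.97 to 11.7 ± 0.399 CPM. Ednrb, the endothelin receptor of migrating crest, fell from 15.2 ± 7.44 to 5.02 ± 0.104 CPM, a log2 fold change of -1.58 that was -0.98 without untreated replicate 2. Without untreated replicate 2 the list had 2 members higher and 0 lower, and without either dTAG-13 library 3 higher and 0 lower, and the list test passed with upper quartile factors (0.0475) and without dTAG-13 replicate 2 (0.00849).

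**Figure D2:**
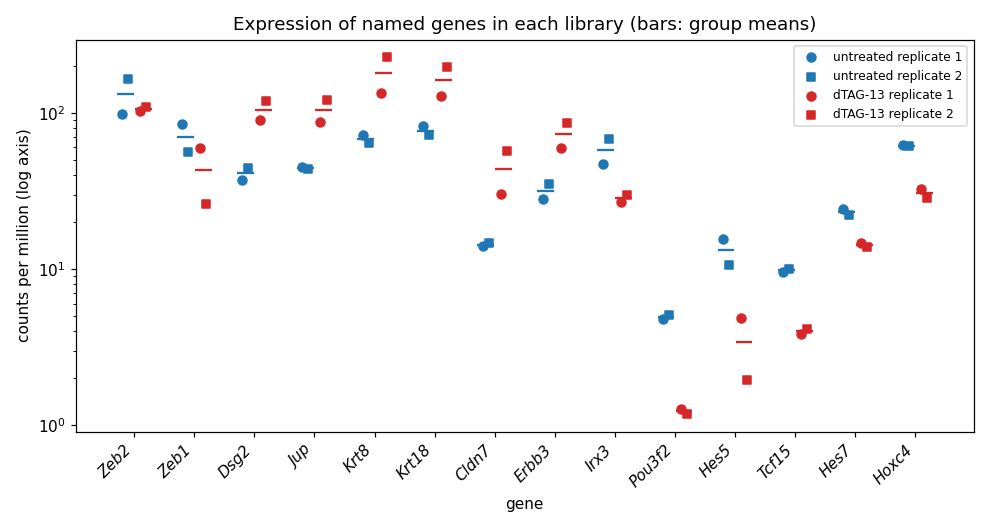
Depth-normalised read counts (CPM) of 14 named genes in each library on a log axis, untreated in blue and dTAG-13 in red, replicate 1 as circles and replicate 2 as squares, with short bars for the group means. Krt8 runs from 63.8 and 71.7 CPM untreated to 133 and 226 CPM with dTAG-13, and Pou3f2 from 4.82 and 5.07 CPM to 1.28 and 1.19 CPM.

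The 5 genes with the smallest p in each direction are given as values, since none was called by edgeR over all genes. Higher with dTAG-13 were Dsg2 (chromosome 18, 20558074 to 20604526), a desmosomal cadherin, at 41.0 ± 5.16 and 104.3 ± 21.1 CPM, and Jup (chromosome 11, 100368856 to 100397839), the plakoglobin of desmosomes and adherens junctions, at 44.6 ± 0.996 and 104.2 ± 24.0 CPM (SD, n = 2 each). The protease gene Tmprss13 was at 1.97 ± 0.232 and 12.6 ± 3.99 CPM, the signalling ligand gene Wnt4 at 2.78 ± 0.655 and 12.8 ± 1.16 CPM, and the actin nucleator gene Fmn1 at 12.8 ± 1.21 and 30.4 ± 1.83 CPM. Lower were Hoxc4, Dmrt2 and Ptn, described with their lists, Lrig1, a receptor-tyrosine-kinase regulator, at 99.7 ± 2.03 and 56.1 ± 0.422 CPM, and the septin gene Septin3 at 67.1 ± 10.8 and 33.96 ± 2.88 CPM. Their adjusted p was 0.756 in edgeR, except 0.809 for Ptn and Septin3. DESeq2 called all 10, with adjusted p from 7.44e-05 for Dsg2 to 0.00842 for Septin3.

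The other cell types and states gave fewer differences. Counts past the threshold in this paragraph and the next are edgeR's over each list alone, and DESeq2's were not set beside them. Mesenchymal genes had a median of -0.28 with 0 of 23 past the threshold (adjusted p = 0.0825), and endothelial genes a median of -0.40 with 0 of 18 (0.312). Cdh2, which encodes N-cadherin, was at 230.0 ± 6.68 and 182 ± 55.4 CPM, and Pecam1 was at 18.3 ± 0.501 and 24.3 ± 1.49 CPM. The medians of both lists turned positive without untreated replicate 1, to 0.48 and 0.79, or without dTAG-13 replicate 2, to 0.17 in both. Both lists moved in opposite directions when single libraries were left out. Each such fit leaves the replicate numbers unequal between the groups. Mesenchymal and endothelial genes were lower in number 2 (median log2 differences of -1.06 and -1.49), so the number enters these values with the treatment. The endothelial list was higher without untreated replicate 1 (adjusted p = 0.0121) or dTAG-13 replicate 2 (0.0382) and lower without untreated replicate 2 (7.84e-05) or dTAG-13 replicate 1 (5.94e-04). The mesenchymal list was lower without untreated replicate 2 (2.77e-05) or dTAG-13 replicate 1 (3.43e-07) and higher without dTAG-13 replicate 2 (0.0226). WNT responses had a median of 0.07 with 0 of 19 past the threshold (0.264), where Apcdd1 and Rnf43, which are WNT antagonists, had log2 fold changes of 1.15 ± 0.28 and 0.94 ± 0.22. FGF and ERK responses had a median of 0.09 with 0 of 18 (0.192), where Spry1 had 0.60 ± 0.14 and Fgf17 0.35 ± 0.14; the list passed without untreated replicate 2 (0.0119). Notochord genes had a median of 0.25 with 0 of 10 past the threshold (0.372). Neuromesodermal progenitor and tail bud genes had a median of 0.01 but a mean of -0.08 and a list test that pointed down (0.896), with 0 of 19 past the threshold, Epha5 at -0.63 ± 0.23 and Evx1 at 0.89 ± 0.23. That list passed as lower without untreated replicate 1 (0.0269) and as higher without untreated replicate 2 (0.0467). Cardiac genes had a median of -0.09 but a mean of 0.09 and a test that pointed up (0.850), with 0 of 15, and passed in opposite directions too, higher without untreated replicate 1 (1.60e-04) or dTAG-13 replicate 2 (0.0382) and lower without untreated replicate 2 (0.00191). Of primitive blood genes only Runx1 and Epor were measured, at log2 fold changes of 0.30 and -0.04, and the list was not tested.

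Lists of cell state had medians between -0.14 and 0.31. Integrated stress response genes had a median of -0.14 with 0 of 18 past the threshold (adjusted p = 0.0196, or adjusted p = 0.512 with an estimated correlation), with Psat1 at -0.41 ± 0.18 and Chac1 at -0.68 ± 0.30. The p53 response had a median of -0.09 with 0 of 18 (adjusted p = 0.0446, or adjusted p = 0.437 with an estimated correlation), with Eda2r at -0.28 ± 0.14. Immediate early genes had a median of 0.14 with 0 of 14 (adjusted p = 0.0370, or adjusted p = 0.416 with an estimated correlation), with Klf6 at 0.40 ± 0.14 and Zfp36 at 1.03 ± 0.36. The stress response call was lost without untreated replicate 1 (0.2215) or dTAG-13 replicate 2 (0.482), the p53 call without untreated replicate 2 (0.785), dTAG-13 replicate 1 (0.181) or dTAG-13 replicate 2 (0.116), with no filter (0.0812) or without members shared with other lists (0.0879), and the immediate early call without untreated replicate 2 (0.269) or dTAG-13 replicate 1 (0.435). Over the same settings the medians of the stress response ran from -0.27 to -0.13, of the p53 response from -0.19 to -0.07 and of immediate early genes from 0.15 to 0.33, the extremes being without dTAG-13 replicate 1 and dTAG-13 replicate 2, untreated replicate 1 and untreated replicate 2, and dTAG-13 replicate 1 and dTAG-13 replicate 2. Proliferation genes had a median of -0.01 with 0 of 20 (0.486), cholesterol synthesis genes 0.04 with 0 of 20 (0.452) and replication-dependent histone genes 0.10 with 0 of 18 (0.0825). Hypoxia and glycolysis genes had a median of -0.04 with 0 of 19, a mean that rounds to 0.00 and a test that pointed up (0.893), with Ndrg1 at 0.60 ± 0.26. Without dTAG-13 replicate 2 cholesterol, histone and hypoxia lists passed as higher (0.00849, 0.00849 and 0.0311). Mitochondrial transcripts had a median of 0.31 with 0 of 7 past the threshold (adjusted p = 0.0196, or adjusted p = 0.626 with an estimated correlation), and the call was lost without untreated replicate 1 (0.578, median -0.02), dTAG-13 replicate 1 (0.0769) or dTAG-13 replicate 2 (0.116, median 0.18), while the median was 0.76 and 6 members rose over the list alone without untreated replicate 2. Their share of gene counts was 1.26% and 1.91% in the untreated libraries and 1.72% and 2.06% with dTAG-13. This share rests on the 7 measured of 13 mitochondrial genes. The others had 0 or 1 counts in every library, so it is not the full mitochondrial content. Untreated replicate 1 had the lowest share and also the most reads outside genes, 35.65% of its reads in genes, outside genes or ambiguous, against 24.1% to 29.2% in the others.

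Simulated changes of 2-fold were recovered in 5% of 100 genes and of 4-fold in 74% when the observed difference between replicate numbers was put into the counts and the test left it out, and in 46% and 91% when it was not put in. The count of 0 called genes therefore belongs to a test that misses most 2-fold changes where libraries differ by number, and does not show that single genes did not change. For list tests, 20 simulated lists were shifted by 0.6 on the log2 scale, and camera called all 20 at the preset correlation and 0 with an estimated one. At the preset correlation it also called 1 of 200 lists that were not shifted. Those lists were random genes with no correlation of their own, and their counts held no difference between replicate numbers. The simulation therefore does not test whether the preset value suits the real lists. Estimated correlations of real lists reached 0.66 for epithelial genes and 0.96 for mesenchymal genes. They come from a fit without the replicate number and so hold the difference between numbers. In that difference 13 of 23 mesenchymal genes were called. The test with an estimated correlation called 0 of the 20 shifted lists, so its misses do not show that a list did not move.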

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

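The alternative without members shared between lists was chosen after seeing the data; the others given here were not. Of the 19 lists called, 7 kept their direction and their call in every setting of the camera test at the preset correlation, libraries left out included: epithelial genes, neural tube progenitor, somite, gut endoderm, pluripotency, Hox groups 1 to 4, and BMP, TGF-beta and SMAD responses. None kept it with an estimated correlation or with fry. The count of 0 genes called was the same with both other scalings, both other filters, the legacy fit, the stricter thresholds, thinned counts, without mitochondrial and the 50 highest genes, and without any one library. DESeq2 called 27 genes higher and 14 lower. Depth differed little between libraries, and with 2 libraries per group leaving one out leaves a lone library whose spread is assumed. The numbers are then unequal between the groups, so part of a change on leaving out a library can come from the difference between numbers. Except where a sentence says otherwise, the cause of a difference between settings was not tested.

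The replicate numbers are shared by both groups, but no label ties a number to a culture or a day. What a number stands for cannot be told from 2 pairs, and the main test was fixed without it. The numbers were therefore not used to pair the libraries there. The values that follow show a difference shared by same-numbered libraries, which a test without the number counts as spread. Deviations of same-numbered libraries from their group means correlated at 0.631 across genes, and after a trend on GC content and transcript length was subtracted the value was 0.656, against 0.644 before over the 13259 genes with both, which argues against such a bias as the source of the shared deviations. Chi-square per degree of freedom was lower between libraries of the same number (24.9 and 22.9) than between replicates of a group (36.3 and 30.9). The first principal component, with 59.3% of the variance, separated the numbers and the next, with 27.3%, the groups. With the replicate number as a block, edgeR called 398 genes higher and 247 lower and DESeq2 114 higher and 46 lower. Over all genes, edgeR's calls with the block held 29 of 33 epithelial, 12 of 25 BMP, 10 of 21 pluripotency and 8 of 19 gut endoderm members, all higher. They held 12 of 20 neural tube progenitor, 9 of 16 somite and 8 of 12 members of Hox groups 1 to 4, all lower. All 41 genes that DESeq2 called without the block, and 158 of its 160 calls with it, were among edgeR's 645 calls with the block. The log2 fold change of Zeb1 was then called, at -0.79 in edgeR and -0.80 in DESeq2. In the simulation with the observed difference between numbers, the block recovered 88% of 2-fold and 100% of 4-fold changes with 24 false calls. Those false calls are a larger share of the calls than the threshold of 0.05 sets. In the block fit of the real counts the median prior degrees of freedom were infinite, so the spread of a typical gene came from the trend over genes. List tests with the block called endothelial (adjusted p = 5.37e-04) and mesenchymal genes (3.99e-05), which missed 0.05 with fry and the block (0.316 and 0.194) and with an estimated correlation and no block (0.875 and 0.825). They missed differentiating neuron (0.0694), immediate early genes (0.0841) and the p53 response (0.106). Hypoxia and glycolysis turned direction with 0.869.

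The split of the 4 libraries by treatment called 0 genes, the split by replicate number 437, and the remaining split, untreated replicate 1 and dTAG-13 replicate 2 against the others, 0. The same splits gave 19, 18 and 1 of 32 lists at the preset correlation and 0 for each split with an estimated one. A split by number that calls more genes than the treatment points to a structure of the libraries that follows the numbers, and 3 splits are too few for a share under 0.05.

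Adjusted p-values of lists that lost their call with an estimated correlation were 0.416 for somite, primitive streak, neural tube progenitor, differentiating neuron, gut endoderm, epithelial, BMP, retinoic acid, both tested Hox and immediate early genes, 0.425 for presomitic mesoderm, 0.437 for pluripotency, primordial germ cell and the p53 response, 0.512 for the integrated stress response, 0.599 for NOTCH, 0.626 for mitochondrial transcripts and 0.649 for intermediate and lateral plate mesoderm. With fry they were 0.323 for Hox groups 1 to 4, 0.748 for mitochondrial transcripts, 0.853 for retinoic acid, 0.861 for lateral plate and NOTCH, and 0.7405 for the other lists that had been called. Neuromesodermal progenitor and hypoxia lists turned direction, both at 0.994. With fry and the block they were 0.186 for presomitic mesoderm, primitive streak, neural tube progenitor, gut endoderm, lateral plate, pluripotency, BMP and immediate early genes, 0.194 for somite, retinoic acid and Hox groups 1 to 4, 0.227 for primordial germ cell and epithelial genes, 0.3475 for the integrated stress response, 0.408 for NOTCH and Hox groups 5 to 9, 0.4435 for differentiating neuron, 0.5685 for the p53 response and 0.571 for mitochondrial transcripts. Fry asks whether a list moves one way and not whether it moves more than other genes.

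Differentiating neuron missed 0.05 with RLE factors (0.0579), upper quartile factors (0.0832), at least 50 counts (0.1865), thinned counts (0.0959) and without the highest genes (0.0746), and the p53 response with no filter (0.0812). Upper quartile factors called the neural crest list (0.0475) and turned neuromesodermal progenitors (0.958). That list also turned with at least 50 counts (0.773), as did cardiac genes (0.930), and without the highest genes (0.981), as did hypoxia (0.930). Without members shared with another list, fewer genes were tested and lateral plate and retinoic acid (both 0.0522), primitive streak (0.0564) and the p53 response (0.0879) missed 0.05, while NOTCH (0.438) and cardiac genes (0.888) turned direction.

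Without each library in turn, adjusted p-values ran over these lowest and highest values. Among lists called with all libraries, they ran from 0.0239 to 0.186 for Hox groups 5 to 9, 8.61e-05 to 0.664 for NOTCH, 0.0218 to 0.206 for differentiating neuron, 0.00849 to 0.435 for immediate early genes, 0.00233 to 0.482 for the integrated stress response, 1.12e-08 to 0.785 for lateral plate, 3.36e-06 to 0.578 for mitochondrial transcripts (turned without untreated replicate 1), 0.00701 to 0.785 for the p53 response, 1.08e-06 to 0.0649 for presomitic mesoderm, 4.00e-05 to 0.161 for primordial germ cell and 0.00480 to 0.352 for retinoic acid. Among the others, they ran from 0.0119 to 0.569 for FGF and ERK, 1.60e-04 to 0.206 for cardiac, 0.00849 to 0.580 for cholesterol synthesis, 7.84e-05 to 0.0382 for endothelium, 0.0311 to 0.785 for hypoxia, 3.43e-07 to 0.0995 for mesenchymal genes, 0.00849 to 0.409 for neural crest, 0.0269 to 0.435 for neuromesodermal progenitors, 0.0790 to 0.615 for notochord, 0.0940 to 0.635 for proliferation, 0.00849 to 0.768 for histones and 0.0644 to 0.706 for somite derivatives. All of these others except neural crest turned direction without at least 1 library. Log2 fold changes that turned sign ran from -0.65 to 0.10 for Zeb2, -3.62 to 1.07 for Emcn, -0.34 to 2.11 for Emx2, -1.01 to 0.30 for En1, -0.37 to 0.43 for Epor, -0.34 to 4.32 for Hoxd10, -1.93 to 0.55 for Lbx1, -0.28 to 0.0115 for Rrm2, -0.50 to 0.80 for Runx1 and -0.00827 to 0.65 for Slc2a3. None of these 10 genes was called with all libraries. Among other named genes not called over their list, the values moved over 1.5 times, from -0.69 to -0.08 for Cdh2, 0.04 to 2.03 for Hoxa10, -0.76 to -0.25 for Hoxa9, -0.86 to -0.19 for Hoxc8, -1.57 to -0.68 for Hoxb1, -1.76 to -0.91 for Crabp2, -0.98 to -0.42 for Dll1, 0.64 to 1.49 for Bmp2, 0.67 to 1.49 for Smad6, 0.76 to 1.43 for Apcdd1, 0.26 to 0.69 for Ifitm3, 0.33 to 0.88 for Ndrg1, -0.64 to -0.23 for Psat1 and 0.60 to 1.35 for Zfp36. Medians of lists not called that turned sign ran from -0.80 to 0.74 for somite derivatives, -0.28 to 1.02 for neural crest, -0.37 to 0.33 for neuromesodermal progenitors, -0.12 to 0.19 for WNT, -0.27 to 0.15 for hypoxia, -0.10 to 0.03 for proliferation, -0.14 to 0.16 for cholesterol synthesis and -0.02 to 0.19 for histones. Those of cardiac, endothelial and mesenchymal genes ran from -0.83 to 1.105, -1.445 to 0.79 and -1.08 to 0.48.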

Other observations

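Tests of gut endoderm, of dilution, of a later start, of reads outside genes and of 28S carry-over were chosen after the results they bear on had been seen, as was leaving out each library in the tests of gut endoderm, surface ectoderm, dilution and a later start, and the surface ectoderm list was written once the leading genes were known. DESeq2's 41 calls hold genes that the text above leaves out, most of them outside the fixed lists, and those named here were chosen after their values were seen. Higher with dTAG-13 were Trim29, a keratin-binding protein of stratified epithelia (log2 fold change 3.13 ± 0.54, SE, adjusted p = 7.44e-05), the adhesion receptor gene Nectin4 (2.45 ± 0.52, 0.00255), the homeobox gene Dlx5 (2.32 ± 0.54, 0.00787), the membrane protein gene Prom2 (2.30 ± 0.59, 0.0336) and the desmosomal cadherin gene Dsc2 (0.90 ± 0.19, 0.00255). Lower were Rfx4, a transcription factor of the neural tube (-2.85 ± 0.61, 0.00255), Scube2, which helps release hedgehog ligands (-2.42 ± 0.61, 0.0260), and, from the neural progenitor list, Sox1 (-1.72 ± 0.42, 0.0185).

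The libraries numbered 1 and those numbered 2 differed in genes of several tissues in both groups. Comparing the numbers with edgeR over all 4 libraries called 437 genes, 329 higher in number 1 and 108 higher in number 2. Kdr, the VEGF receptor of endothelial progenitors, was at 103 and 80.4 CPM in the number 1 libraries (untreated, dTAG-13) and at 12.8 and 15.45 CPM in number 2 (adjusted p = 5.49e-04). Over all genes, 8 of 18 endothelial, 6 of 15 cardiac, 13 of 23 mesenchymal and 5 of 15 lateral plate genes were higher in number 1, and 4 of 19 neuromesodermal progenitor and 4 of 16 retinoic acid genes in number 2. Col1a1, the collagen gene of connective tissue, was at 27.3 and 21.9 CPM in number 1 and 5.16 and 2.63 CPM in number 2 (0.00383), and Cdx1, a posterior homeobox gene, at 3.99 and 3.41 against 29.4 and 29.5 CPM (8.06e-04). Camera called the endothelial (adjusted p = 3.35e-13), mesenchymal (2.21e-16) and cardiac lists (1.44e-10), with adjusted p = 0.580, 0.601 and 0.580 with an estimated correlation. Epithelial, neural progenitor and somite lists, which camera called with dTAG-13, also differed between numbers. In number 2 epithelial genes had a median log2 difference of 0.71 (camera adjusted p = 0.00161), neural progenitor genes of 0.50 (0.00494) and somite genes of -0.76 (0.00338), each with adjusted p = 0.675 with an estimated correlation. Pluripotency genes were also higher in number 2 (median 0.52, camera adjusted p = 1.15e-04). Gut endoderm genes (-0.22, 0.0217) and BMP, TGF-beta and SMAD responses (-0.29, 0.0416) were lower. With an estimated correlation camera gave adjusted p = 0.675, 0.675 and 0.716 for these lists. Hox groups 1 to 4 had a median difference of 0.09 and were not called by camera (0.680).

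One pattern is the rise of epithelial genes with dTAG-13. The tables argue against untreated replicate 1 as its source, without which the median log2 fold change was 1.06, and against GC content or transcript length, after which it was 1.15. More gut endoderm-like cells stay open: epithelial genes outside the endoderm list lay 0.81 above endoderm genes outside the epithelial list (95% interval 0.50 to 1.11), but only 0.42 without untreated replicate 1 (-0.41 to 0.64) and 0.16 without dTAG-13 replicate 2 (-0.39 to 0.46). Both of these fits leave the replicate numbers unequal between the groups, so the difference between numbers enters them. More surface ectoderm-like cells remain a candidate explanation, since a list of 18 measured genes, 3 of them in a fixed list, had a median of 0.93 (0.63 to 1.23), which was 0.24 without dTAG-13 replicate 2, with none called over the list alone and a camera p of 2.86e-09 that was 0.0965 with an estimated correlation. Release of repression by ZEB2 within the same cells, the explanation the design names, cannot be told apart from added cells, because both would raise the 31 of 33 members that were higher in both numbers and bulk counts do not separate cells.

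Another is the lower level of neural progenitor genes, for which 2 explanations were tested and neither was excluded. Dilution of all other cells by added epithelial cells would lower neural and mesenchymal genes alike, and their medians differed by -0.73 (-1.60 to -0.27) with all libraries. The difference was 0.15 (-0.62 to 0.55) without untreated replicate 2 and 0.14 (-0.60 to 0.90) without dTAG-13 replicate 1, where the replicate numbers are unequal between the groups. Mesenchymal genes were lower in number 2 (median -1.06), so these values mix number with treatment. Within numbers 1 and 2 the medians were -0.92 and -1.18 for neural and -0.11 and -0.38 for mesenchymal genes, which argues against dilution alone. These medians carry no interval, and the difference did not hold without each library, so dilution was not excluded. A later start of the same sequence would lower Hox groups 5 to 9 at least as much as groups 1 to 4, and the difference went the other way, at -0.39 (-0.72 to -0.04), though its interval reached 0.11 without untreated replicate 2 and 0.17 without dTAG-13 replicate 1. Other medians are mixed: as a later start would give, pluripotency (0.50, and 0.08 to 0.79 without each library) and primitive streak genes (0.57, 0.32 to 0.71) were higher and somite (-0.59, -1.10 to -0.40), presomitic (-0.32, -0.61 to -0.09) and differentiating neuron genes (-0.23, -0.455 to -0.15) lower, while neuromesodermal progenitors (0.01, -0.37 to 0.33) and the 3 measured members of Hox groups 10 to 13, higher in both numbers with a median of 0.78 and none called, did not follow it. Fewer neural progenitor-like cells, or lower expression in as many cells, stay open as effects of the treatment and were not tested. The series holds no cells without the degron given dTAG-13 and no measure of ZEB2 protein. Effects of the compound itself therefore cannot be told apart from loss of ZEB2, for these genes or for the epithelial genes.

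For the difference between replicate numbers, the tables argue against 2 technical sources. The share of reads outside genes differed between number 2 and number 1 by -11.5 percentage points in the untreated group and by 3.93 in the dTAG-13 group, and the share of the 28S ribosomal RNA gene Rn28s1 by 2.18 and -1.87, so neither moved with the numbers in one direction. A difference in the cell types that the aggregates formed, or in their stage, between cultures may lie behind it, but no label gives a culture or a date and no biological explanation was tested.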
